A study of Oryza sativa with 6 samples.

How the data were processed

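Leaf blades of HMG-GFP rice seedlings were fixed with 1% formaldehyde for 30 min, chromatin was sheared by sonication, and IP libraries were made after pull-down with a GFP antibody, per the labels' protocols. Input libraries were made without antibody. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic 0.33, Bowtie2 2.4.1 and MACS2 2.1.2, with no roles or settings, and which tool called the peaks is not stated. The lists have a grid of 200 bp, gaps of at least 800 bp and a pileup column proportional to the fold, features of a caller that joins windows into islands rather than of usual MACS2 output, so the caller is uncertain and widths, numbers and folds of peaks may be those of such islands. The genome build, annotation, read filters and the role of the inputs in peak calling are not given in the sources used here. Peaks were called per replicate, since each IP sample has its own list, with its own peak names. How the inputs entered the fold would change every fold, and cannot be examined from the lists.

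Each list gives, per the file headers, a start, end, length, fold enrichment, p-value, FDR and a column named pileup. The fold enrichment is a linear ratio as deposited by the authors. The deposited pileup is the fold times a constant in each list (0.674, 0.603 and 0.726), so it was treated as a ratio and not as a read depth. The deposited p-value and FDR are those of the authors' caller, and the FDR is never above 1e-05; 3774, 1085 and 798 p-values are printed as 0. The grid and the gaps were tested on all rows of the lists. Such a grid sets the resolution of every position to 200 bp, and joining of windows across shorter gaps would lengthen peaks and lower their number. Starts count from 0 in the files and are printed here counting from 1.

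Peaks on the 12 nuclear chromosomes were used for the comparisons. The length of a chromosome was taken as the last base under any peak. Overlap was at least 1 bp; overlapping peaks of the 3 lists were merged, and a shared region holds a peak of each replicate. The value of a region in a replicate is the highest fold of that replicate's peaks in it. Chance was estimated with 1000 circular shifts of the peaks within each chromosome, with p counted one-sided. The named regions are the 10 shared regions with the highest median fold and the 5 widest, a rule fixed before the data were examined, as were the tests and alternatives unless the text says otherwise. Windows of 1 Mb and the stretch of chromosome 4 were chosen after the data were examined. The split of peaks into deciles by fold, the classes of regions by replicate and the counts of identical peaks were not among the fixed rules either. The overlap test was tested on simulated data: with 60035 replicate 1 peaks and the replicate 2 peaks placed at random, 0 of 20 simulations gave p under 0.05, and with 30% of replicate 1 peaks copied into the other list, 20 of 20 did. The simulated peaks were placed uniformly along each chromosome, with fewer shifts per test than the 1000 used for the results. The simulations therefore do not show how the test behaves with the regional clustering of the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

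Alternatives were a stricter FDR, a fold of at least 2, a reciprocal overlap of 50%, lists of equal length (the top 41474 of each by FDR), regions in 2 or more replicates, shorter shifts, and leaving out each replicate. The fixed rules also asked for positions relative to genes, 39 phosphate homeostasis genes and other gene lists, and base composition. These were not analysed here, because the gene table at hand is for another assembly: its last gene ends past the last peak by 0.159 Mb on chromosome 8 and by 4.46 Mb on chromosome 9. Peaks on the sequences named ChrSy and ChrUn are given apart.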

Results

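Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map where OsHMGB1, a rice chromatin protein of the high mobility group B family, sits along the genome. HMGB proteins are abundant non-histone proteins that bind and bend DNA with little sequence preference. The series, by its title, deals with this protein in phosphate homeostasis and plant growth. Leaf blades came from transgenic plants carrying HMG-GFP, a fusion to green fluorescent protein, and an antibody against GFP recovered the bound chromatin. The seedlings had grown for 28 d in a condition labelled HP, which the labels do not spell out. The 6 samples form 2 groups, 3 immunoprecipitates (IP) and 3 matching inputs, that is, sheared chromatin without antibody. Each IP replicate has a peak list, and no values of the inputs by themselves were analysed here. Every comparison below is therefore between the 3 IP replicates, or between their peaks and shifted positions. The labels do not say whether the replicates came from separate plants, so spreads cover only the difference between these samples. The p-values ask only whether peaks of these lists coincide in position more than shifted peaks do. The lists give no read counts and the depth of the libraries is unknown.

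HMG-GFP peaks were numerous, short and spread over all 12 nuclear chromosomes. Replicate 1 had 60158 peaks, replicate 2 had 56916 and replicate 3 had 41526, a mean of 52867 ± 9954 (SD, n = 3). On the nuclear chromosomes the median peak was 1400 bp wide in replicates 1 and 2 and 1600 bp in replicate 3, and 90% of peaks were no wider than 4000, 4200 and 3800 bp. Peaks covered 118 Mb of the 373 Mb spanned by the lists in replicate 1 (31.7%), 120 Mb in replicate 2 (32.1%) and 80.7 Mb in replicate 3 (21.6%), a mean of 28.5% ± 5.96 (SD, n = 3). Peaks with a fold of at least 2 covered a mean of 61.3 Mb, against 106 Mb for all peaks. The enrichment in most peaks was modest. The fold enrichment, a value per peak given by the authors, had a median of 2.84 in replicate 1, 2.17 in replicate 2 and 2.03 in replicate 3. It reached 2 or more in 83.0%, 59.8% and 52.8% of peaks, and its highest values were 14.4, 7.71 and 8.77. Wider peaks tended to have lower folds: across peaks of one list the Spearman rho between width and fold was -0.36 in replicates 1 and 2 and -0.16 in replicate 3. Peaks of one list are not independent replicates, so these coefficients carry no p-value.

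The first question the replicates can answer is whether peaks stood at the same places each time. No immunoprecipitate from plants without HMG-GFP was among the samples. Recurrence alone therefore cannot separate HMG-GFP binding from other sources of recurring peaks. Peaks recurred at the same places more often than shifted peaks did. Of the replicate 1 peaks, 90.3% overlapped a replicate 2 peak by at least 1 bp, and 66.8% overlapped a replicate 3 peak. Of the replicate 3 peaks, 89.9% were met in replicate 1 and 92.7% in replicate 2. Of the replicate 2 peaks, 93.1% were met in replicate 1 and 70.7% in replicate 3. Since the peaks cover so much of the genome, circular shifts of one list along each chromosome still gave 37.1% to 54.3% on average. The observed shares were 1.66 to 1.85 times the shifted ones, and none of 1000 shifts reached the observed share in any of the 6 comparisons (one-sided circular-shift permutation test, p = 0.001 in each, the smallest that 1000 shifts can give). When at least 50% of a peak's length had to be covered, the shares were 61.5% to 89.8% and the ratio to shifted lists was 2.54 to 3.06. With the top 41474 peaks of each list, the lowest of the 6 shares was that of replicate 3 peaks met in replicate 1, 76.0%. With a fold of at least 2, the share of replicate 1 peaks met in replicate 3 was 42.8%.

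**Figure D1:**
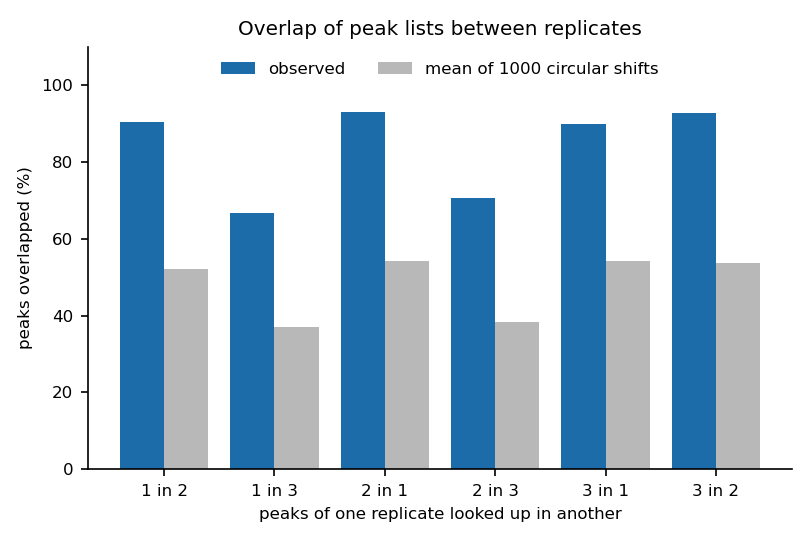
Percentage of the peaks of one replicate that overlapped a peak of another by at least 1 bp (y axis) for the 6 ordered pairs of replicates (x axis, "1 in 2" meaning replicate 1 peaks looked up in replicate 2). Blue bars are the observed shares, 66.8% to 93.1%, and grey bars the mean of 1000 circular shifts, 37.1% to 54.3%; the lowest observed shares are those of replicate 1 and 2 peaks looked up in replicate 3.

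Merging overlapping peaks of the 3 lists gave 60991 regions, of which 35791 (58.7%) held a peak of every replicate. Another 25.2% held peaks of 2 replicates and 16.1% a peak of 1 replicate. The shared regions had a median width of 2000 bp, and 85.1% of them were made of exactly 1 peak from each replicate. Shifted lists gave 14407 such regions on average and at most 14759 (one-sided circular-shift permutation test, p = 0.001, the smallest possible). The difference was larger when bases were counted in place of regions: 56.7 Mb lay under peaks of all 3 replicates, 15.2% of the span, against 8.47 Mb in shifted lists, a ratio of 6.69. Shifts of 10 to 100 kb, which keep the regional density of peaks, gave 9.35 Mb, a ratio of 6.06. The number of shared regions depended on replicate 3 and on the fold. Regions held by replicates 1 and 2, with replicate 3 left out, numbered 51427, with 105 Mb under both lists. Peaks with a fold of at least 2 gave 17848 shared regions and 28.4 Mb under all 3 replicates, 17.6 times the shifted length. The shifted length falls as lists cover less, here from 8.47 Mb to 1.61 Mb. The higher ratio alone therefore does not show closer agreement. For the lists of 2 replicates, which overlap more by chance, the length under both was 2.74 times the shifted length without replicate 3, 2.44 without replicate 1 and 2.24 without replicate 2.

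Strong peaks recurred more often than weak ones. In replicate 1, 26.0% of peaks in the lowest decile by fold were met by both other replicates, against 96.5% in the highest decile. In replicate 2 the shares were 19.1% and 95.7%. No shifted level was computed per decile. Shifted peaks of all folds met replicate 3 alone at 37.1% on average for replicate 1 and 38.3% for replicate 2. The shares of the lowest deciles are therefore not shown to exceed chance. Peaks in these deciles were also wider, with median widths of 2200 and 2800 bp against 1400 bp in each full list. Over all deciles, both others met 65.8% of replicate 1 peaks and 67.4% of replicate 2 peaks. These shares are close to the 66.8% and 70.7% met by replicate 3, whereas replicates 1 and 2 met 90.3% and 93.1% of each other's peaks. The trend in replicates 1 and 2 thus mostly shows which peaks replicate 3 had, and it was not split by partner replicate. Replicate 3 peaks were met often at every strength, from 77.1% in the lowest decile to 93.1% in the highest. Across the 35791 shared regions, the rank agreement of the fold was highest between replicates 1 and 2 (Spearman rho 0.67) and lower between replicates 2 and 3 (0.55) and between replicates 1 and 3 (0.44). Regions are not independent replicates, so the coefficients are given without a p-value. Ranking by the authors' p-value in place of the fold gave 0.89, 0.81 and 0.74 for the same pairs.

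**Figure D2:**
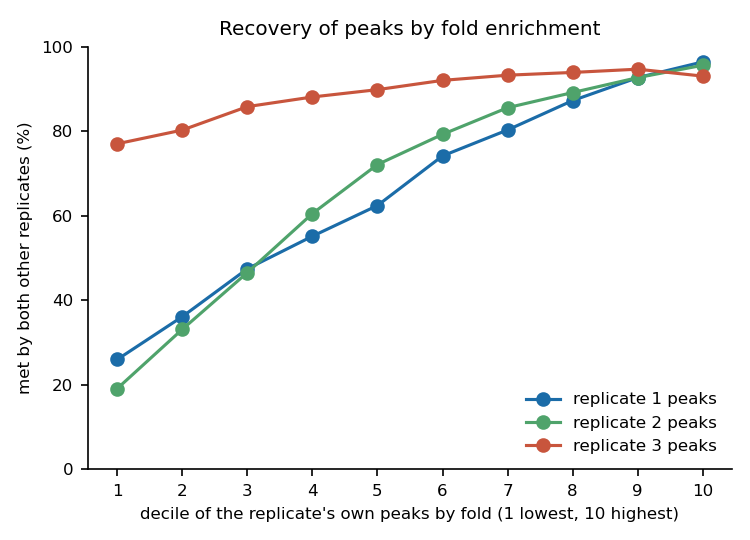
Percentage of peaks met by peaks of both other replicates (y axis) in each decile of a replicate's own peaks ordered by fold enrichment (x axis), 1 line per replicate. The share climbs from 26.0% to 96.5% in replicate 1 and from 19.1% to 95.7% in replicate 2, while in replicate 3 it is 77.1% or more in every decile.

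The 10 shared regions with the highest median fold lay on 6 chromosomes and were 400 to 1800 bp wide, except for 1 of 5000 bp. A high median over the replicates does not require a high fold in each of them. Positions count from 1 in the coordinates of the lists, whose genome build is not given in the sources used here, and no gene was assigned to them. The region with the highest median fold over the replicates was on chromosome 11 from 12123201 to 12123600, 400 bp wide, with folds of 14.4, 7.71 and 3.39 in replicates 1, 2 and 3. The next was on chromosome 1 from 37507001 to 37512000, 5000 bp wide, with folds of 9.19, 7.71 and 2.35. Its fold in replicate 3 was below the upper quartile of the folds in that list, 2.37. A region of 800 bp on chromosome 2 from 35186201 to 35187000 had folds of 8.01, 7.56 and 4.36, and one of 1600 bp on chromosome 5 from 24446601 to 24448200 had 9.75, 7.27 and 3.69. On chromosome 1, the region from 41108601 to 41109800 had folds of 7.21, 7.01 and 2.93, and the one from 24804401 to 24806200 had 9.21, 6.77 and 3.02. On chromosome 2, the region from 27654801 to 27655600 had folds of 10.9, 6.99 and 2.73. On chromosome 4, the region from 28608401 to 28609400 had 8.69, 6.97 and 3.99, and the one from 23576801 to 23577400 had 6.82, 7.44 and 3.80. The remaining region, on chromosome 3 from 34226601 to 34227800, had folds of 7.05, 6.77 and 2.90. Replicate 3 had the lowest fold in each of these 10 regions, and whether folds of different lists share a scale is not stated. This is not particular to them: in 24975 of the 35791 shared regions the fold was highest in replicate 1 and lowest in replicate 3.

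The 5 widest shared regions measured 37600 to 55800 bp. The widest, 55800 bp on chromosome 10 from 7056801 to 7112600, joined 5 peaks of replicate 1, 2 of replicate 2 and 2 of replicate 3, with highest folds of 3.51, 2.01 and 3.04. A region of 46600 bp near the start of chromosome 6, from 46001 to 92600, was 1 peak in each replicate, with folds of 1.62, 1.19 and 1.196. The others were 40400 bp on chromosome 2 from 31861601 to 31902000 (folds 2.54, 1.66 and 1.54), 39400 bp on chromosome 5 from 11115401 to 11154800 (2.56, 1.45 and 2.43) and 37600 bp on chromosome 7 from 18269401 to 18307000 (2.004, 2.16 and 2.69). Peaks of 10 kb or more numbered 958 in replicate 1, 884 in replicate 2 and 157 in replicate 3.

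Shared regions were densest on chromosomes 3, 1 and 2, with 118, 114 and 112 per Mb, and sparsest on chromosomes 12, 11 and 10, with 72.1, 75.9 and 84.5 per Mb. The other chromosomes had between 88.3 and 96.2 per Mb. Each single list had its highest density on chromosome 3 and its lowest on chromosome 12. The ratio between the highest and lowest chromosome was 1.21 in replicate 1, 1.252 in replicate 2 and 1.59 in replicate 3. For shared regions it was 1.63, and 1.29 with replicate 3 left out.

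Within chromosomes, replicates 1 and 2 covered nearly the same windows, and replicate 3 left out long stretches that they covered. Across 368 windows of 1 Mb, the covered share of a window had a Pearson r of 0.92 (Spearman rho 0.92) between replicates 1 and 2, 0.68 (0.66) between replicates 2 and 3 and 0.40 (0.39) between replicates 1 and 3. Windows are not independent replicates, and no p-value is given. One stretch of low replicate 3 coverage, chosen after its values were seen and not ranked against others, was the first 18 Mb of chromosome 4. There peaks covered 31.9% of the sequence in replicate 1, 29.6% in replicate 2 and 9.15% in replicate 3, whereas the rest of the chromosome was covered to 36.2%, 38.8% and 34.1%. Peaks in those 18 Mb also had lower folds within each list, with medians of 2.36, 1.79 and 1.89 against 3.18, 2.39 and 2.09 in the rest of the chromosome. The contrast between replicates 2 and 3 was smaller without the low-fold peaks: with a fold of at least 2, the stretch was covered to 18.4%, 6.13% and 3.41% in replicates 1, 2 and 3 and the rest to 30.5%, 23.3% and 19.8%. The ratio of the stretch to the rest was then 0.60, 0.26 and 0.17, against 0.88, 0.76 and 0.27 with all peaks. It was 0.73, 0.60 and 0.27 with lists of equal length and 0.82, 0.57 and 0.21 with a -log10 q of at least 20. The windows with the least sequence under peaks of all 3 replicates were 18000001 to 19000000 on chromosome 6 (2.82%), 12000001 to 13000000 on chromosome 5 (3.36%) and 10000001 to 11000000 on chromosome 4 (3.56%). In the first of these, peaks covered 45.5% in replicate 1, 36.7% in replicate 2 and 3.46% in replicate 3. The windows with the most were 9000001 to 10000000 on chromosome 3 (32.7%) and 24000001 to 25000000 on chromosome 4 (30.9%), where the replicates covered 41.0%, 45.6% and 45.2%, and 37.3%, 40.6% and 40.8%.

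**Figure D3:**
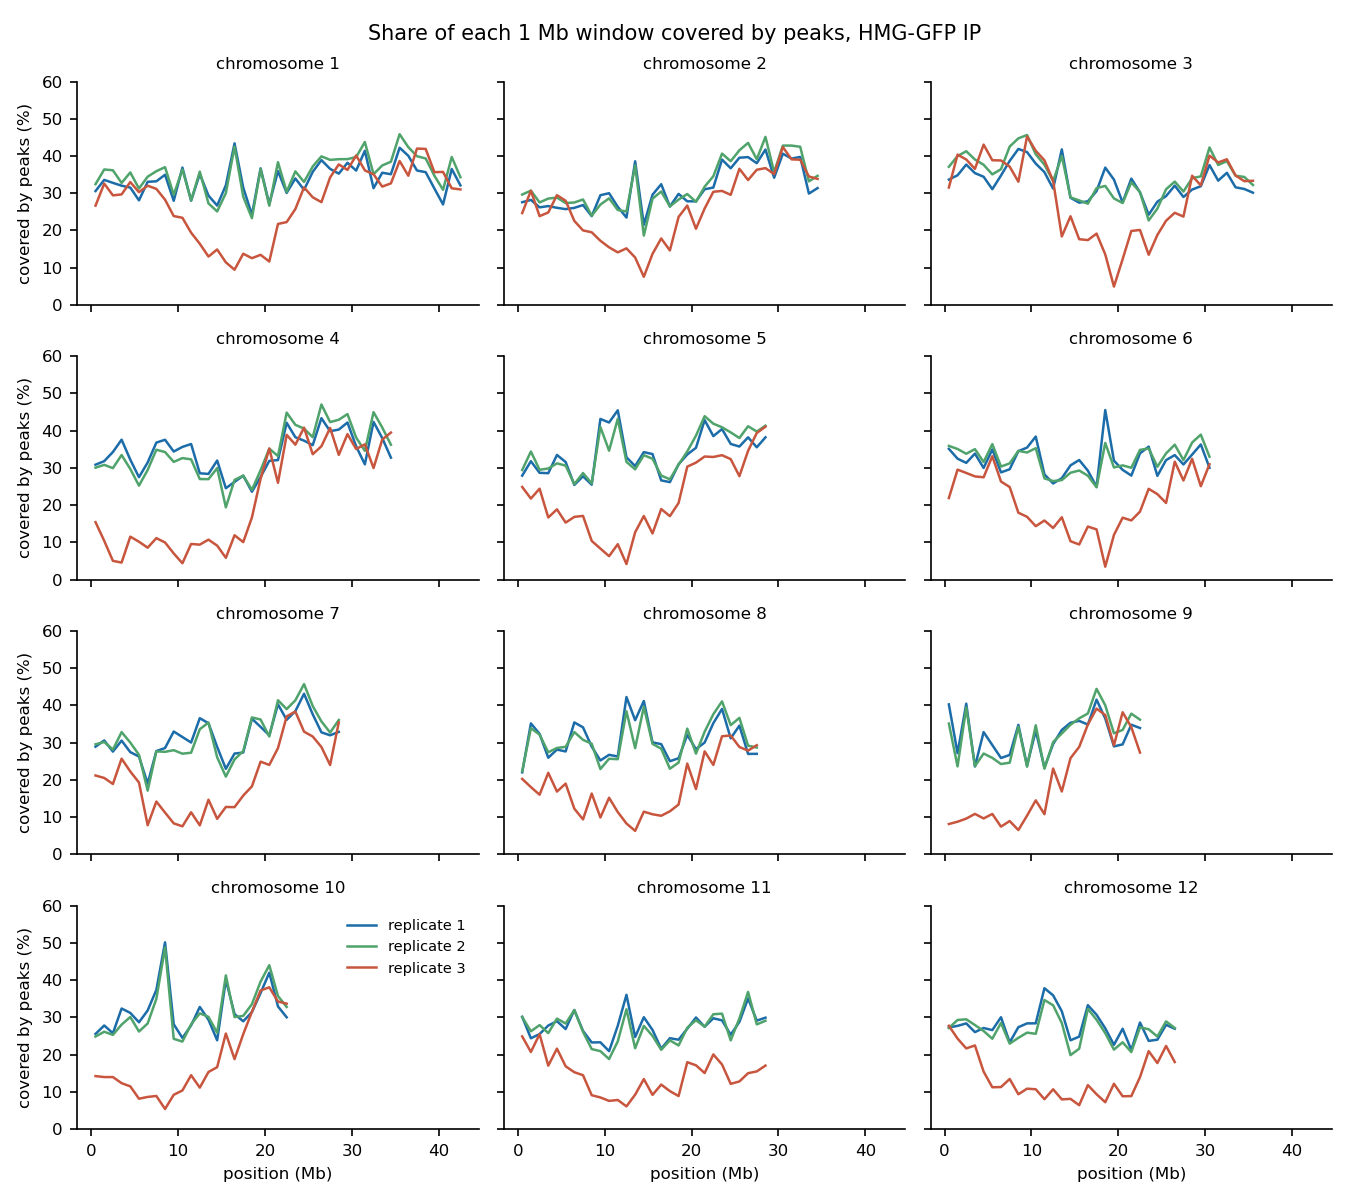
Percentage of each 1 Mb window covered by peaks (y axis) against position in Mb (x axis) on the 12 nuclear chromosomes, 1 line per IP replicate. Replicates 1 and 2 run together (Pearson r 0.92 over 368 windows), while replicate 3 drops in long stretches, such as the first 18 Mb of chromosome 4, where it covers 9.15% against 31.9% and 29.6%.

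The stretches that replicate 3 left out were mostly those where the peaks of replicate 1 had low folds. When the windows were ordered by the mean fold of replicate 1, the lowest quintile was covered to 33.3% in replicate 1, 30.6% in replicate 2 and 9.31% in replicate 3. The highest quintile was covered to 34.8%, 37.7% and 35.9%. The covered share in replicate 3 followed the mean fold in replicate 1 across windows (Spearman rho 0.94) more closely than it followed the covered share in replicate 1 (0.39). With peaks of a fold of at least 2 only, the ratio of the lowest to the highest quintile was 0.53 in replicate 1, 0.25 in replicate 2 and 0.18 in replicate 3, against 0.96, 0.81 and 0.26 with all peaks.

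**Figure D4:**
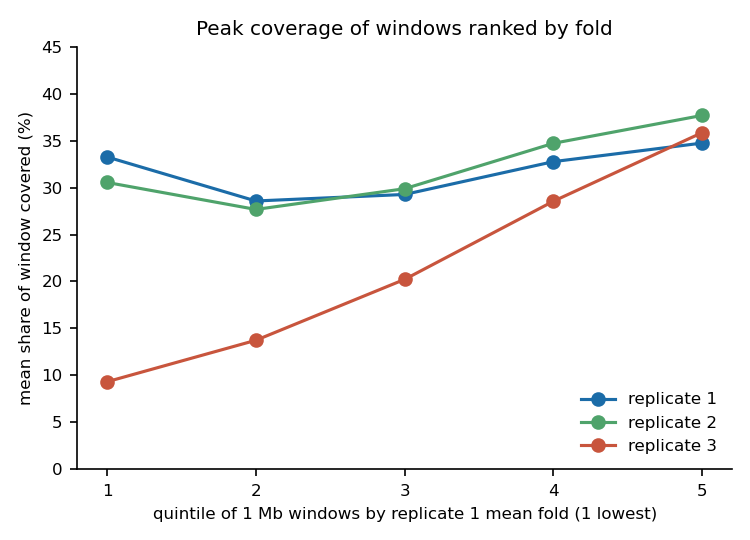
Mean percentage of a 1 Mb window covered by peaks (y axis) in quintiles of the 368 windows ordered by the mean fold enrichment of replicate 1 peaks (x axis), 1 line per replicate. In the lowest quintile replicate 3 covers 9.31% against 33.3% and 30.6% in replicates 1 and 2, and in the highest quintile the values are 35.9%, 34.8% and 37.7%.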

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

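The test on the fold percentile of narrow peaks and the one on chromosome 4 were chosen after the results were seen; the other tests in this part were set before their results, on patterns already noticed.

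Peaks also stood on the 2 sequences outside the 12 chromosomes, which the comparisons did not use. ChrSy held 103, 89 and 41 peaks in replicates 1, 2 and 3 (mean 77.7), covering 33.6%, 28.8% and 11.4% of its spanned length. ChrUn held 20, 15 and 11 (mean 15.3), covering 5.32%, 3.70% and 1.61%.

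Replicate 3 covered 9.31% of the windows where replicate 1 folds were low, against 33.3% and 30.6% in replicates 1 and 2. With replicate 2 reduced to as many peaks by p-value, its ratio of lowest to highest quintile was still 2.33 times that of replicate 3. This was beyond the excess of 25% set in advance, so dropping the least significant replicate 2 peaks did not give so low a ratio. A p-value ranking can keep wide peaks of low fold, however. In replicate 2 the Spearman rho of width and fold was -0.36, and 48.8% of peaks of 10 kb or more lay in the lowest 2 quintiles. Those quintiles hold 74 windows each of the 368, so this share was only somewhat above their share of the windows. Cutting the list of replicate 2 is also not the same as a weaker or shallower library. Such a library was not tested, so a loss of less significant peaks by that route stays open. With replicate 2 reduced by fold, its ratio was 1.23 times that of replicate 3, within that excess. The windows were themselves ordered by fold, which sets the direction of the test by fold. On the first 18 Mb of chromosome 4 against the rest the list reduced by p-value gave 2.23 times and the one reduced by fold 1.31 times, but that stretch was picked for its low coverage in replicate 3, so neither of these 2 values counts for or against an explanation. A loss of low-fold peaks everywhere stays open. A different background in the third input was not tested. The replicates belong to 1 group, so no biological explanation was tested.

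Peaks of 10 kb or more were 958 and 884 in replicates 1 and 2 and 157 in replicate 3. If they were neighbouring peaks joined across short gaps, replicate 3 would show the parts. The median number of replicate 3 peaks inside those of replicate 1 was 0, because 63.8% held none, and a replicate without peaks there cannot show parts; this bound was therefore wrongly set. Of the 347 that held any, 20.2% held 2 or more. Joining and continuous binding cannot be told apart for these peaks, and no biological explanation was tested.

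The highest folds stood in narrow peaks: the top 1% by fold had a median width of 800, 800 and 600 bp in the 3 replicates. Chance placement of the narrow peaks is argued against. Of 122 replicate 1 peaks of at most 400 bp in that top 1%, 116 were met by replicate 3 (95.1%, Wilson 95% interval 89.7% to 97.7%). The interval treats peaks of one list as independent, which they are not, and does not cover variation between replicates. The share was 4.92 percentage points below that of peaks of 1 kb or more, and widths in between were not compared. Shifted replicate 1 peaks of all widths met replicate 3 at 37.1% on average, and narrow ones were not shifted apart. Recurrence cannot separate binding from other sources of recurring peaks. Whether chance raised the fold of narrow peaks stays open. The median percentile of the fold in replicate 3 was 68.8 for the narrow and 93.5 for the wide peaks, a gap of 24.7, but in replicate 2 it was 88.6 and 97.8, a gap of 9.21, under the 10 points the test required. No biological explanation was tested.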

How the results depend on the processing

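All overlaps between replicates stayed above those of shifted lists, with p = 0.001 in each of the 6 pairs, under the 6 alternatives run, in circular-shift permutation tests, while the shares themselves ranged from 42.8% to 92.4% with a fold of at least 2 and from 76.0% to 88.4% with equal lists. The planned FDR alternative removed no peak, so it says nothing; a -log10 q of at least 20 and shifts of 10 to 100 kb were added after the data were seen. With a fold of at least 2, a cut set across lists whose common scale is not stated, shared regions fell to 17848, the length under all 3 lists to 28.4 Mb, the mean covered length to 61.3 Mb and the mean of the median widths to 1267 bp, and the ratio of highest to lowest chromosome density rose to 2.02. With a -log10 q of at least 20 that ratio was 1.93 and the width 1600 bp, and equal lists gave 1600 bp too. Regions in 2 or more replicates gave a ratio of 1.24. The rank agreement of replicates rose to 0.89, 0.74 and 0.81 for the pairs 1 and 2, 1 and 3, and 2 and 3 with -log10 p; the cause was not tested for any of these. Leaving out a replicate gave 36447 to 51427 shared regions, 57.9 to 105 Mb under all lists used, density ratios of 1.29 to 1.62, mean peak numbers of 49143 to 58424, median widths of 1400 to 1500 bp, median folds of 2.103 to 2.51 and 99.6 to 119 Mb covered; the highest region number and the lowest ratio are those without replicate 3. A reciprocal overlap of 50% with a peak of each other replicate was met by 26328 replicate 1 peaks, against 680 with shifts. These are peaks of replicate 1 and not merged regions. The pileup is proportional to the fold, so ranking by it changes nothing. Alternatives on genes, gene lists and base composition were not run. No paired analysis was possible because the inputs have no peak list here. The depth is unknown, so a missing peak in replicate 3 is not shown to be missing binding.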

Other observations

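Regions held by replicates 1 and 2 and not by replicate 3 formed the second largest class of merged regions, 13460 or 22.1%. Their median width was 1800 bp and their median folds were 2.27 in replicate 1 and 1.67 in replicate 2, against 3.30 and 2.46 in the regions shared by all 3. Of these regions, 29.4% lay in the quintile of windows with the lowest replicate 1 fold and 9.94% in the highest quintile, whereas the shared regions were placed the other way, 10.6% and 28.3%. The quintiles are ordered by replicate 1 fold, in which these classes differ, so part of this placement is built in. Regions of replicate 1 alone were placed likewise, 32.6% and 8.12%. Regions of replicate 3 alone numbered 2587, with a median width of 600 bp, and 25.5% of them lay in the highest quintile.

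Replicates 1 and 2 had 25979 peaks with identical start and end, 43.3% of replicate 1 and 45.7% of replicate 2. Replicate 3 had 8190 such peaks in common with replicate 1 and 10751 with replicate 2, 19.7% and 25.9% of its own list. The mean fold per 1 Mb window ranked almost identically in replicates 1 and 2 (Spearman rho 0.99 across windows) and less so between replicate 3 and replicates 1 and 2 (0.68 and 0.69).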
